A study of Mus musculus with 6 samples.

How the data were processed

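Gene expression was measured in 6 libraries of single cells from the cardiac region of mouse embryos, 1 library for each of 3 stages (E8.25, E8.75 and E9.25) and 2 treatments (control, and retinoic acid given to the dam at E7.25). Each library pooled 3 litter-mates, dissociated with trypsin, per the labels' protocols. Libraries were made with the 10x Genomics single cell 3' kit, per the labels' protocols. The deposited matrices hold raw UMI counts per gene and barcode from Cell Ranger, per the file headers. The submitters' processing notes name Cell Ranger 2.1.1, the mouse build mm10 and Seurat, whereas the file headers give Cell Ranger 3.1.0 for the 3 control matrices and 5.0.0 for the 3 RA-exposed ones. The software version therefore coincides with the treatment. The counting of introns and the use of strand are not given in the sources used here. The control matrices hold 31055 features, which include EGFP and tdTomato, and the RA-exposed ones hold 31053, and the 31053 shared genes were compared. Of these, 30934 were matched by identifier to GENCODE M21 on GRCm38, from which coordinates, gene types and transcript lengths were taken.

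The median number of UMIs per barcode was 17769, 6402 and 13285.5 in the control libraries in stage order and 27676, 15183.5 and 16148.5 in the RA-exposed ones. Barcodes with at least 1500 detected genes and at most 10% mitochondrial counts were kept, which left 11047, 7470 and 14612 control and 7968, 8418 and 13585 RA-exposed cells. Doublets were called with Scrublet as implemented in scanpy 1.11.5, library by library, at an expected rate of 0.8% per 1000 cells. It called 298 (2.70%) and 845 (5.78%) cells at E8.25 and E9.25 in controls and 221 (2.77%), 363 (4.31%) and 1159 (8.53%) in RA-exposed libraries. In the E8.75 control the caller marked under 0.5% of cells, so the top 5% of scores were taken instead, which was 371 cells. Called doublets were removed.

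Each library was clustered on its own from 2000 variable genes, 30 principal components and a graph of shared neighbours (20 per cell), with the Leiden method of igraph 0.11.9 at resolution 1. Clustering of all libraries together had been tried first. It was set aside because several clusters held only cells of the RA-exposed E8.75 library. With genes then centred within each library, mesoderm of the E8.25 control fell into 1 mixed cluster, and this too was set aside. Clustering by library, the thresholds for naming clusters, the fallback for doublets and leaving sex-linked and reporter genes out of clustering were all decided after the files were read. A cluster was named after the class with the highest mean z score of its markers, from 20 marker sets fixed before the data were examined. Naming needed at least 3 markers at 2-fold or more over the rest of the library (with a prior of 5 CPM) and in at least 20.0% of its cells. A cluster stayed unnamed when its 10 leading genes held more markers of another class than of its own, or when its median UMI count was under 1/3 of its library's with no own marker among those genes. Cardiomyocyte-like cells were clustered again (1000 variable genes, 15 components) and named from 3 sets of chamber markers under the same rules. Unnamed clusters held 1948, 984 and 1427 control and 1821, 1467 and 1461 RA-exposed cells. No authors' annotation of cells was used here, so names are rebuilt, and a name can differ from the one the study gave. Markers of a class are not reported among its named genes, but can appear as members of a gene list, such as Smpx and Tnni1 in cardiomyocyte-like cells.

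Raw counts were summed per library and class and tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr, the quasi-likelihood F test, and Benjamini-Hochberg adjustment with a threshold of 0.05. The RA-exposed against control test had stage as block and the E9.25 against E8.25 test had treatment as block, each over all 6 libraries with 2 residual degrees of freedom. Classes with at least 20 cells in every library were tested. Cells were never used as replicates. Within a stage, and between control stages, 2 libraries were compared without a test, as log2 ratios of CPM with a prior of 1 CPM, and each sum was given an exact Poisson interval of 95%. Shares of cells were given exact (Clopper-Pearson) binomial intervals of 95%. These intervals cover counting error only, and a count of 0 was read as allowing up to 3 counts.

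Named genes followed a rule fixed at the same time. In a tested comparison these were the 10 genes with the largest change in each direction (3 in classes other than cardiomyocyte-like and all cells) with an adjusted p under 0.05, the same sign in all 3 stage pairs (in both treatments for the stage comparison) and a mean of at least 10 CPM in the higher groups. In a comparison of 2 libraries they were the 5 largest log2 ratios in each direction with at least 20 CPM and 50 counts in the higher one. Ribosomal, mitochondrial, haemoglobin and predicted genes were counted but not named. Of each list up to 4 members with at least 10 CPM in 1 library were named.

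The 22 gene lists, also fixed then, cover the retinoic acid response, Hox genes of paralogue groups 1 to 6, sarcomere and contraction, ventricular chamber, atrial and sinus venosus, second heart field and outflow tract, FGF, BMP, canonical Wnt targets, Hedgehog, Notch, S phase, G2 and mitosis, cell cycle inhibitors, p53 targets and apoptosis, glycolysis and hypoxia, oxidative phosphorylation, extracellular matrix, dissociation and heat stress, left-right and dorsal mesocardium, sex-linked genes, and haemoglobin, taken in advance as a sign of RNA from blood. Across stages they were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01. They were tested again with an estimated one, and both were adjusted over the 22 lists. The estimated version rests on the 2 residual degrees of freedom, so hardly any list could pass it. Failing it does not show that correlation between genes explains a list, and the preset value was not checked on these data. Within a stage a list's median was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. Several genes belong to more than 1 list. The sarcomere list holds all 14 markers that name the cardiomyocyte class.

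The reporter was read only in controls. Each cell was thinned to 5000 UMIs and shallower cells were left out. For each gene, 50-base windows in the last 500 bases of its transcripts were searched in other genes' transcripts, and a gene with over 50.0% shared windows was reported as uncertain. Cells were typed by sex from UMIs of Xist and of Y-linked genes. The trend with transcript length was fitted in each library by lowess with a span of 0.3. It was fitted on each gene's log2 CPM relative to its mean over the libraries, over genes with a mean of at least 1 CPM. Spearman's rho of log2 fold change with transcript length was taken over genes with a mean of at least 10 CPM.

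The pipeline was tested on simulated data with 200 changed genes, drawn from those with a mean of at least 10 CPM. Dispersions were those estimated from the same 6 libraries. The simulated groups differed only by the changes put in, so the data held no length trend or batch difference between them. Recovery of genes below that level, such as most Hox genes measured in cardiomyocyte-like cells, was not tested. For the RA comparison in cardiomyocyte-like cells it recovered 83 of 100 genes changed by 2-fold and 100 of 100 by 4-fold, with 20 false calls among 13232 genes, which is a larger share of the calls than the nominal rate. For the stage comparison it recovered 55 and 100 of 100, with 15 false calls among 13353 genes, and for all cells 39 and 97 of 100, with 14 among 17818.

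Alternatives fixed in advance were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, other cell filters (1000 genes and 20%, or 2500 genes and 10%), doublets kept, Leiden resolution 2, markers left out of clustering, sums thinned to the smallest library, no block and leaving out each stage pair. Those added after the data were seen were cells typed as male, sex-linked genes left out, the length trend removed, all libraries clustered together, low-UMI cardiomyocyte clusters left out, clusters second closest to cardiomyocytes added, and sub-clusters led by markers from outside the heart left out. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9 was used.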

Results

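Single-cell RNA was measured in mouse embryos carrying Foxa2Cre and the mTmG reporter, in which cells descended from Foxa2-expressing cells carry EGFP. The cardiac region, with the endoderm, head folds and pharyngeal structures around it, was taken at E8.25 (cardiac crescent), E8.75 (primitive heart tube) and E9.25 (heart tube). At each stage 1 control library and 1 RA-exposed library were made, the latter from embryos whose dams had received retinoic acid (RA, 3.25 mg/kg) by injection on E7.25, each from 3 pooled litter-mates, so that 6 groups hold 1 library each. The control libraries held 287788071 UMIs in 14355 barcodes at E8.25, 292582247 in 13036 at E8.75 and 305860144 in 21318 at E9.25. The RA-exposed libraries held 263502030 UMIs in 8789 barcodes, 183218045 in 11260 and 316680253 in 17566 at the same stages. After filtering, 10749, 7099 and 13767 control cells and 7747, 8055 and 12426 RA-exposed cells were kept. There was no replicate library in any group, so intervals on single libraries cover counting error only.

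The first question was how large the cardiomyocyte-like population was, with and without retinoic acid, as the heart tube formed. Cardiomyocyte-like clusters, named from 14 markers such as Actc1, Myl7, Ttn and Tnnt2, made up 3.31% of control cells at E8.25, 13.9% at E8.75 and 18.6% at E9.25. In RA-exposed embryos they made up 8.52%, 10.4% and 11.9% at the same stages. RA-exposed embryos thus held a larger share of cardiomyocyte-like cells than controls at E8.25 and a smaller one at E9.25. The log2 ratio of the shares was 1.36 (95% interval 1.17 to 1.55) at E8.25, -0.43 (-0.56 to -0.29) at E8.75 and -0.65 (-0.74 to -0.55) at E9.25. The E8.25 value was 0.64 with stricter cell filters, 0.88 with low-UMI clusters left out and 6.37 with all libraries clustered together, where 9 control cells remained in the class.

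Sums of the 14 cardiomyocyte markers over all kept cells moved the same way as the shares. They stood at 1118, 10679 and 14769 CPM in controls and at 2334, 5596 and 5613 CPM in RA-exposed embryos. The clusters that held the class shared leading genes in part between the groups compared. At E8.75 the control class lay in a Nppa and Myl2 cluster of 471 cells and a Vsnl1 and Wnt2 cluster of 334 cells. A low-UMI cluster of 183 cells, with Tdgf1 and Acta2 among its leading genes, also belonged to it. The RA-exposed class lay in a Nppa, Nppb and Myl2 cluster of 599 cells and a Tdgf1 and Acta2 cluster of 235 cells. At E9.25 the largest control cluster, with 702 cells, was led by Nppa, Myl2 and Pln, while the largest RA-exposed cluster, with 611 cells, was led by Myh6, Tnni3 and Fbxo32. At E8.25 a single cluster of 356 control cells faced RA-exposed clusters of 473 and 187 cells, each led by Myl7, Myl4 and Tnnt2, and the smaller one was low in UMIs.

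Sub-clusters named from fixed chamber markers gave 98, 0 and 620 ventricular-like cells in controls and 0, 181 and 126 in RA-exposed libraries, in stage order. These counts depend on which sub-clusters met a name. E9.25 RA-exposed sub-clusters of 275 cells led by Ccnd2, Nppa and Hey2 and of 178 cells led by Cited1 met none. In the E8.75 control, sub-clusters of 128 cells (with Nppa and Myl2) and 80 cells (with Cited1 and Nppa) met none. Nor did an RA-exposed E8.25 sub-cluster of 121 cells with Tdgf1, Myl2 and Irx2 among its leading genes. Before sub-clustering, E9.25 clusters led by Nppa and Myl2 held 702 control and 345 RA-exposed cells, beside 179 RA-exposed cells in a cluster led by Cited1 and Myl2. At E9.25 atrial and venous pole-like sub-clusters held 623 control and 385 RA-exposed cells, and outflow tract-like sub-clusters 441 and 304, of which 149 RA-exposed cells lie in a sub-cluster with haemoglobin genes among its leading genes. At E8.25 no sub-cluster was named atrial or venous pole in the control, while 133 RA-exposed cells were, but a control sub-cluster of 63 cells led by Mab21l2, Kitl, Sfrp5 and Nr2f2 met no name. Of the cardiomyocyte-like cells, 185, 482 and 877 control cells and 412, 190 and 662 RA-exposed cells lay in sub-clusters that met no chamber name. A pair of RA-exposed clusters whose nearest other identity was cardiomyocyte stayed outside the class. These were 266 cells at E8.25 led by Sfrp5, Wnt2 and Tbx5, and 426 cells at E8.75 led by Shox2, Tbx18, Wnt2 and Vsnl1, which are genes of the inflow region of the heart. With them the RA-exposed shares were 12% and 15.6% and the E8.75 log2 ratio turned to 0.17, while no control cluster was added. Shares also depend on where the tissue was dissected.

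**Figure D1:**
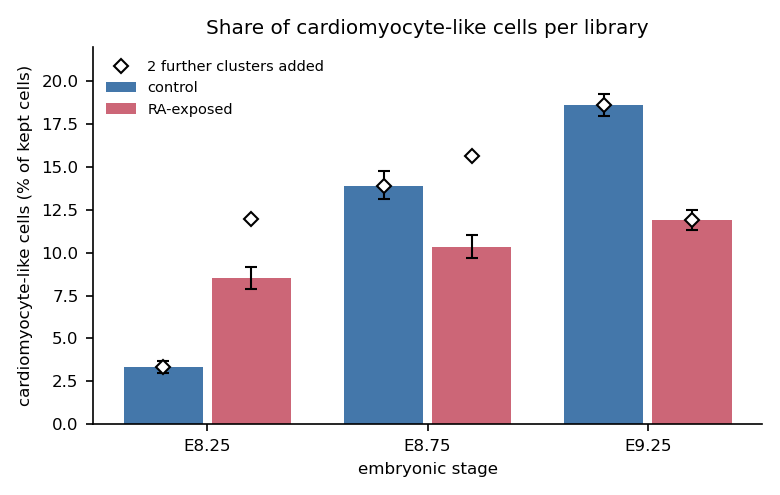
Share of kept cells (percent) that fell in cardiomyocyte-like clusters, by stage, for control and RA-exposed libraries (1 library per bar). Error bars are exact 95% binomial intervals for counting error, and open diamonds show the share with the 2 further clusters added. The RA-exposed share is 8.52% against 3.31% in control at E8.25 and 11.9% against 18.6% at E9.25.

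The stage comparison asked how cardiomyocyte-like cells changed between the crescent and the heart tube. Nppa and Pln had the largest rises among the genes named. Nppa, the atrial natriuretic peptide of the embryonic chambers, rose by 6.62 ± 0.60 (log2 fold change ± SE, E9.25 over E8.25, edgeR adjusted p = 0.000511), from 7.19 to 1947 CPM in controls and from 20.2 to 958 CPM in RA-exposed cells. Pln, the phospholamban that restrains the calcium pump of the sarcoplasmic reticulum, rose by 5.86 ± 0.54. Adprhl1, a pseudoenzyme needed for chamber outgrowth, rose by 5.65 ± 0.59, although it had 0 counts in the E8.25 control, so that its fold depends on the prior count. The same holds for Cav1, which encodes the coat protein of caveolae and rose by 5.55 ± 0.78. Shox2, a transcription factor of the sinus venosus and pacemaker region, rose by 4.87 ± 0.36, and Tnc, which encodes the matrix protein tenascin C, by 4.68 ± 0.34. Mlip (a lamin-interacting muscle protein), Vnn1 (a pantetheinase), the lincRNA AC167229.1 and Sspn (sarcospan, of the dystrophin complex) rose by 4.58, 4.55, 4.44 and 4.35.

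Lefty2 had the largest fall among the genes named. Lefty2, a Nodal antagonist of the left lateral plate, fell by 8.21 on the log2 scale (SE 0.60, edgeR adjusted p = 0.000289), from 56.0 to 0.085 CPM in controls. Ifitm1, expressed in early mesoderm, fell by 5.34, Aplnr, the apelin receptor of migrating cardiac progenitors, fell by 4.39, Lhx1, a LIM homeobox factor of gastrulation, fell by 4.34 and Phlda2, an imprinted growth regulator, fell by 3.87. S100g, a calcium-binding protein, fell by 7.11. The remaining named genes that fell mark other tissues: Apom fell by 7.66, Apob fell by 7.04 and Apoa1 fell by 6.31, apolipoproteins of the yolk sac and liver, and Spink1, a marker of foregut endoderm, fell by 4.78. Hepatic and yolk sac endoderm-like cells numbered 1458 of the kept control cells at E8.25 and 124 at E9.25, but 144 and 267 of the RA-exposed cells, in which Apoa1 (log2 ratio -3.13) and Spink1 (-2.79) were lower at E9.25 too.

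Of the fixed gene lists, sarcomere genes moved upward as a whole. The list holds all 14 markers that named the class, so its values are not independent of which clusters were named. All 27 sarcomere and contraction genes had positive changes with a median of 1.03, and 13 rose over all genes tested and 19 adjusted over the list alone, including Myl2 (4.18), Tnni3 (3.50) and Smpx (2.14). In the ventricular chamber list 8 of 13 rose and 1 fell over all genes, against 9 and 1 adjusted over the list alone, with a median of 1.59. In the atrial and sinus venosus list 7 of 16 rose, against 9 up and 1 down adjusted over the list alone, with a median of 1.31 and with Tbx18 (3.91) and Nr2f1 (3.05) among them. All 20 oxidative phosphorylation genes had positive values with a median of 0.55, of which 1 rose over all genes and 3 adjusted over the list alone, among them Atp5o (1.03). Of the 20 S phase genes 19 had negative values with a median of -0.55, of which 3 fell over all genes and 6 adjusted over the list alone, such as Tyms (-1.01). By camera with the preset correlation the adjusted p was 1.4e-14 for sarcomere, 5.1e-07 for ventricular, 1.4e-05 for atrial, 5e-06 for oxidative phosphorylation and 2.4e-06 for S phase genes. With an estimated correlation the adjusted p was 0.510, 0.415, 0.415, 0.510 and 0.515. That version rests on 2 residual degrees of freedom, which left little room for any list to pass.

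Hedgehog genes (median -0.70, camera adjusted p = 0.0123), canonical Wnt targets (-0.78, 0.0454), FGF genes (-0.43, 0.0365) and genes of G2 and mitosis (-0.30, 0.0109) stood lower at E9.25. With an estimated correlation their adjusted p was 0.510, 0.510, 0.515 and 0.515. Adjusted over the list alone, 1 Hedgehog gene rose and 5 fell, 4 Wnt targets fell, 1 FGF gene rose and 3 fell and no G2 and mitosis gene changed. Over all genes the counts were 1 up and 2 down, 3 down, 1 up and 3 down, and 0. Foxf1 (-2.0), Lef1 (-1.01) and Fgf8 (-2.02) fell. Haemoglobin genes, whose source in these cells (free RNA or doublets with blood cells) was not tested, were higher at E9.25 with a median of 3.13 (camera adjusted p = 0.000518, and adjusted p = 0.515 with an estimated correlation).

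The other 12 lists did not pass camera, and their medians were as follows. The retinoic acid response list had a median of -0.24, in which Aldh1a2, the main embryonic enzyme of retinoic acid synthesis, fell by 2.41. Hox genes stood at 0.78, second heart field genes at -0.58, BMP genes at 0.20, Notch genes at 0.14 and cell cycle inhibitors at -0.31. The p53 targets stood at 0.07, glycolysis genes at -0.03, extracellular matrix genes at 0.56, stress genes at -0.07, left-right genes at -0.30 and sex-linked genes at 0.04. Single members still changed: Hk1 (3.05), Sema3c (3.39), Col3a1 (2.70), Bmp4 (1.76) and Hey1 (1.52) rose, and Has2 (-2.35) and Tdgf1 (-1.97) fell.

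In all, 927 genes rose and 390 fell of 13884 tested (edgeR quasi-likelihood test with treatment as block, Benjamini-Hochberg adjusted p under 0.05), and all 1317 had the same sign in control and RA-exposed pairs. Of these, 5 were markers that define the class. Without the E8.75 pair 3217 genes were called.

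Neighbouring control stages were then compared without a test. From E8.25 to E8.75 Nppa went from 7.19 (5.56 to 9.15) to 1245 (1234 to 1255) CPM, and Nppb, Lmod2, which elongates the thin filament, Fosb and Cck, a peptide hormone, had log2 ratios of 5.51, 4.61, 4.39 and 4.09. Lefty2 (-4.82), Ifitm1 (-3.95), Aplnr (-3.67), Phlda2 (-3.13) and Apom (-3.08) were lower. From E8.75 to E9.25 Pln (1.98), Pcolce, an enhancer of procollagen processing (1.83), Mlip (1.64), Fuom (1.61) and Shox2 (1.60) were higher. Histone transcripts Hist1h2an (-3.90), Hist1h3b (-3.41), Hist1h3c (-3.36) and Hist1h1e (-3.33) and the immediate early gene Fosb (-3.84) were lower. The sarcomere list had a median log2 ratio of 1.32 in the first step, above every one of 10000 random lists matched on expression, and of 0.17 in the second, at their percentile 94.9. The dissociation and heat stress list stood at 1.12 and then at -0.83 over the same steps.

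The main comparison asked what retinoic acid given at E7.25 changed in cardiomyocyte-like cells. Nppb, the B-type natriuretic peptide of chamber muscle, rose by 2.45 ± 0.22 (log2 fold change ± SE, RA-exposed over control, edgeR adjusted p = 0.0030). Its level was 2.94, 178 and 55.1 CPM in controls and 22.6, 1123 and 249 CPM in RA-exposed cells at the 3 stages. Hopx, a homeodomain-only cofactor of differentiating cardiac progenitors, rose by 1.45 ± 0.17 (edgeR adjusted p = 0.0118). The transcription factors Tshz1 (1.42 ± 0.20) and Gli3 (1.35 ± 0.21), the latter the main repressor of the Hedgehog pathway, rose as well. Nppb (ENSMUSG00000029019) lies on chromosome 4 from 147985788 to 147987205 and Hopx (ENSMUSG00000059325) on chromosome 5 from 77086988 to 77115121 of GRCm38.

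The other genes named as higher were Axl, a receptor tyrosine kinase (1.74), Arg1, an arginase (1.66), Lrrc8a, a subunit of the volume-regulated anion channel (1.43), the imprinted noncoding RNA Mirg (1.43), Rbms3, an RNA-binding protein (1.43), and Xist, the noncoding RNA of the inactive X chromosome (7.65 ± 1.15). Arg1 is a leading gene of a somite-like sub-cluster of 115 cells in the RA-exposed E8.25 library, and with sub-clusters led by markers from outside the heart left out Arg1 (1.28, adjusted p = 0.0627) and Mirg (1.31, adjusted p = 0.0569) no longer passed. The pools differed in sex. Among cells in which either Xist or a Y-linked gene was detected, 0.782%, 20.7% and 0.407% of control cells and 73.1%, 26.1% and 63.1% of RA-exposed cells held Xist, in stage order. Xist had 2 counts in control cardiomyocyte-like cells at E8.25 and 5 at E9.25.

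Among the genes named as lower, AC160336.1, a lincRNA, fell by 5.97 (SE 0.22, edgeR adjusted p = 3.6e-06), from 1139, 523 and 417 CPM to 22.7, 8.30 and 6.63 CPM. Usp50 fell by 3.00, Gstp1 fell by 2.37, Ccdc85b fell by 2.13, Hist1h2ae fell by 1.85 and Eno1 fell by 1.45. Of these, Usp50, Gstp1, Hist1h2ae and Eno1 are uncertain, since 73.8%, 75.2%, 56.1% and 75.2% of the windows at their 3' ends occur in other genes, and 35.0% of those of AC160336.1 do. Mhrt, an antisense transcript of the Myh7 locus, fell by 1.81, and is uncertain because strand handling in the counting is not given in the sources used here. Carmn, a noncoding RNA of smooth and cardiac muscle, fell by 1.55, and Gal, the neuropeptide galanin, fell by 1.41. Apoa1, an apolipoprotein of yolk sac and liver, fell by 3.14. The E8.75 control class held a low-UMI sub-cluster of 142 cells led by Ttr, Apob, Afp and Apoa1, and with such sub-clusters left out Apoa1 fell by 3.19 (adjusted p = 0.045). Hepatic and yolk sac endoderm-like cells numbered 1458, 402 and 124 in controls and 144, 175 and 267 in RA-exposed libraries, and the log2 ratio of Apoa1 was -3.17, -3.29 and -0.21 at these stages. The naming rule asked for the same sign in all 3 stage pairs, which all 47 called genes had.

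**Figure D2:**
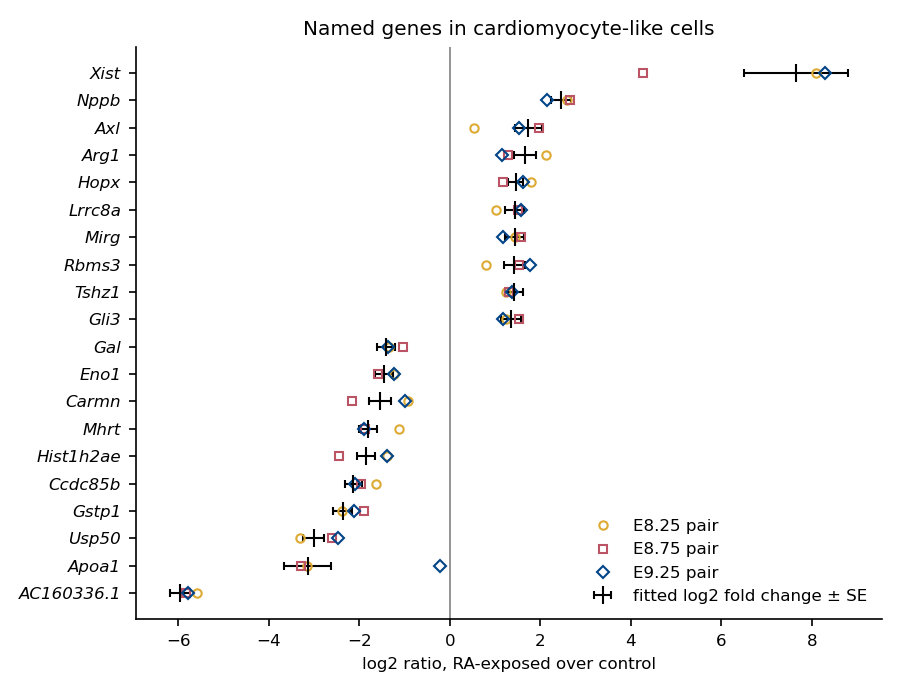
The 20 genes named for RA-exposed over control in cardiomyocyte-like cells. Symbols are log2 ratios of CPM + 1 within each stage (1 library per group), and the fitted log2 fold change over the 3 stages is drawn with its standard error. Every gene has 1 direction in all stages, as the naming rule requires, and Nppb lies between 2.16 and 2.65 within stages.

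Retinoic acid targets and Hox genes stood higher in RA-exposed cardiomyocyte-like cells by camera with the preset correlation, but both had an adjusted p = 0.375 with an estimated correlation. Of 17 retinoic acid response genes 15 had positive values with a median of 0.55, of which 1 rose over all genes tested (Tshz1) and 10 adjusted over the list alone. Among them were Aldh1a2 (0.83 ± 0.28), the orphan receptor corepressor Nrip1 (0.73 ± 0.20) and the homeobox cofactor Meis2 (0.62 ± 0.18). Aldh1a2 and Tbx1 are leading genes of the somite-like RA-exposed sub-cluster, and with such sub-clusters left out Aldh1a2 no longer passed (0.44, adjusted p = 0.216 over the list alone). All 7 measured Hox genes of paralogue groups 1 to 6 had positive values, with a median of 1.24, of which none rose over all genes and 6 adjusted over the list alone. Hoxb2, the only one above 10 CPM, had a value of 0.28 and did not pass. Of 18 second heart field and outflow tract genes 16 had positive values with a median of 0.62. Over all genes 1 rose (Foxc2, 2.08), and adjusted over the list alone 10 rose, and 6 with the trend on transcript length removed. Among the 10 were Tbx1 (1.12, and 0.87 with such sub-clusters left out), Sema3c (1.04) and Fgf10 (0.85). Foxc2 is also in the marker set of paraxial mesoderm and somite, and its value with such sub-clusters left out is not given here. Of 20 extracellular matrix genes 17 had positive values with a median of 0.54, of which none rose over all genes and 12 adjusted over the list alone, such as Col3a1 (1.25), Col1a2 (1.18), Fn1 (1.10) and Tnc (1.07). With the trend on transcript length removed 5 rose adjusted over the list alone and the median was 0.28.

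Among pathways, Notch, Hedgehog and FGF genes stood higher by the same test, and each had an adjusted p = 0.375 with an estimated correlation. In the Notch list 7 of 9 were positive (median 0.70), with 6 rising adjusted over the list alone and none over all genes, among them the ligands Jag1 (1.02) and Jag2 (0.93). In the Hedgehog list 9 of 10 were positive (median 0.85), with 4 rising adjusted over the list alone and 1 over all genes (Gli3), and 2 over the list alone with the trend on transcript length removed. In the FGF list 18 of 19 were positive (median 0.47), with 1 rising adjusted over the list alone (Spry2, 1.48, a feedback inhibitor) and none over all genes, and 3 over the list alone with that trend removed. In the BMP list 14 of 18 were positive (median 0.26), with 2 rising adjusted over the list alone, including Smad6 (0.85), an inhibitor of the pathway, and none over all genes.

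Oxidative phosphorylation and mitosis lists stood lower by camera, and each had an adjusted p = 0.375 with an estimated correlation. Of 20 oxidative phosphorylation genes 17 had negative values with a median of -0.35, and none fell over all genes and 7 adjusted over the list alone, including Ndufv1 (-0.85) and Cyc1 (-0.64). With the trend on transcript length removed 0 fell adjusted over the list alone and the median was -0.23. Of 20 genes of G2 and mitosis 16 had negative values with a median of -0.28, and 1 fell adjusted over the list alone (Cdc20, -1.03) and none over all genes. Haemoglobin genes had negative values in all 6 tested (median -1.50), and none changed by either adjustment.

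By camera with the preset correlation 11 of the 22 lists passed. The adjusted p was 8.4e-05 for the retinoic acid response, 0.000284 for Hox, 8.4e-05 for second heart field, 4.7e-05 for extracellular matrix, 0.000877 for Notch, 0.00119 for Hedgehog, 0.000502 for FGF, 0.000166 for oxidative phosphorylation and 0.00452 for G2 and mitosis genes. With an estimated correlation the adjusted p was 0.375 for each of these. BMP (0.0271) and haemoglobin genes (0.0117) also passed, and their adjusted p was 0.604 with an estimated correlation.

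The other 11 lists did not pass camera. Sarcomere genes had a median of -0.28, of which 1 rose adjusted over the list alone (Ldb3, 0.86) and none over all genes, and Tnni1 had a value of -0.77. With the 2 further inflow-like clusters added the sarcomere median was -0.60, and 13 fell adjusted over the list alone. In the ventricular list (median 0.04) 3 rose and 2 fell adjusted over the list alone, where Nppb stood against Cited1 (-0.99) and Irx4 (-0.97), and 1 rose over all genes. In the atrial and sinus venosus list (median 0.19) 3 rose and 2 fell adjusted over the list alone, where Tbx18 (2.39, also past the threshold over all genes) and Nr2f1 (0.97) stood against Stard10 (-0.98) and Wnt2 (-0.69). Wnt targets had a median of 0.20, S phase genes of -0.10, cell cycle inhibitors of 0.12, for which camera pointed downward, and p53 targets of 0.15, with no gene changed by either adjustment. In glycolysis and hypoxia (median -0.20) Vegfa (1.09) rose and Eno1 and Pfkl (-0.77) fell adjusted over the list alone, and 1 fell over all genes. The dissociation and heat stress list had a median of 0.34 with 1 gene up adjusted over the list alone and none over all genes, and left-right genes had a median of -0.24 with none. With the trend on transcript length removed the dissociation and heat stress list passed camera (median 0.30, adjusted p = 0.0301, 3 up adjusted over the list alone) and 0 sarcomere genes rose. Sex-linked genes had a median of -0.65 and a mean of 0.93, and 1 rose (Xist) and 2 fell adjusted over the list alone, against 1 up over all genes.

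**Figure D3:**
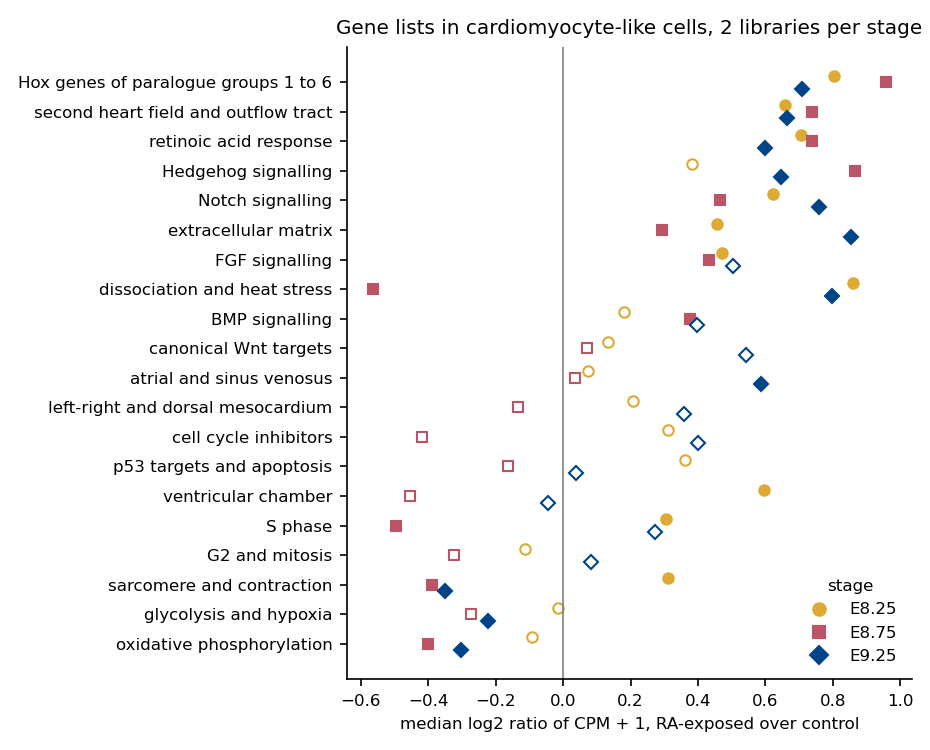
Median log2 ratio of CPM + 1 (RA-exposed over control) of 20 gene lists in cardiomyocyte-like cells within each stage, 1 library per group. Filled symbols lie outside the central 95% of 10000 random lists matched on expression. The retinoic acid response list lies at 0.71, 0.74 and 0.60, and the sarcomere list at 0.31, -0.39 and -0.35.

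Over the 3 stages 27 genes rose and 20 fell of 13409 tested (edgeR quasi-likelihood test with stage as block, Benjamini-Hochberg adjusted p under 0.05). These p-values rest on 6 libraries with 1 per group and 2 residual degrees of freedom, and all controls were processed with one version of the counting software and all RA-exposed libraries with another, so that treatment and batch cannot be told apart. Without the E8.25, E8.75 or E9.25 pair the test called 329, 1043 and 151 genes, and it called 1439 with no filter on low counts, 0 up and 3 down with no stage block, and 1 up and 6 down with called doublets kept. Of the genes named as higher only Nppb kept its call with doublets kept, and none did with no stage block.

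Within single stages, where 2 libraries allow no test, the retinoic acid response and Hox lists stood higher at every stage. The retinoic acid response list had medians of 0.71, 0.74 and 0.60 and the Hox list 0.80, 0.96 and 0.71 in stage order, at percentiles of 99.7 or above among random lists. At E8.25 the class held a sub-cluster of 115 RA-exposed cells led by somite genes such as Tcf15 and Meox1, and without such sub-clusters the medians there were 0.41 (percentile 94.0) and 0.35 (66.8). Second heart field genes stood at 0.66, 0.74 and 0.67. Sarcomere genes were higher at E8.25 (0.31, above every random list) and lower at E8.75 (-0.39, 0.58) and E9.25 (-0.35, 0.020). With the 266 further RA-exposed cells the E8.25 value turned to -0.16, so it depended on which clusters were named cardiomyocyte-like. The dissociation and heat stress list stood at 0.86, -0.57 and 0.80 beside these values.

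At E8.25 Tcf15, a somite transcription factor, stood at 27.9 (25.4 to 30.6) CPM in RA-exposed and 2.61 (1.67 to 3.89) CPM in control cells, a log2 ratio of 3.00. Nppb (2.58), the immediate early genes Egr1 (2.55) and Atf3 (2.47) and Xist (8.09) were also higher there. AC160336.1 (-5.59), Usp50 (-3.32) and the yolk sac and liver transcripts Ttr (-3.61), Apom (-3.32) and Rbp4 (-3.24) were lower. At E8.75 the metallothioneins Mt2 (2.83) and Mt1 (2.76), Nppb (2.65), the gut hormone Pyy (2.13) and Xist (4.26) were higher. Fosb (-4.06), the histone genes Hist1h4h (-3.93), Hist1h2ap (-3.73) and Hist1h3b (-3.18) and AC160336.1 (-5.82) were lower. The E8.75 control stood apart from the other controls in Fosb (3.92, 102 and 6.21 CPM in stage order) and from the E9.25 control in Hist1h3b (37.4 against 2.61 CPM), so that it enters both this contrast and the fall between control stages. At E9.25 Xist (8.29) and the immediate early genes Egr1 (3.14), Junb (2.44), Btg2 (2.23) and Fosb (2.21) were higher, and AC160336.1 (-5.78), Usp50 (-2.47), Gstp1 (-2.11), Ccdc85b (-2.09) and Mhrt (-1.90) were lower.

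The same comparison was made over all cells and in the 6 other classes with at least 20 cells in every library. In sums over all cells AC160336.1 was the 1 gene of 18075 that passed: it fell by 6.23 on the log2 scale (SE 0.25, edgeR adjusted p = 0.0032). At an unadjusted p under 0.05 there were 3506. Hox genes (median 0.91, 10 of 16 rising adjusted over the list alone and none over all genes) and extracellular matrix genes (0.68, 10 of 20 and none) stood higher, by camera with adjusted p = 1.5e-06 and 3.8e-06. With an estimated correlation the adjusted p was 0.422 for both. Col3a1 (2.35), Postn (2.04) and Col1a1 (1.84) led the matrix genes and Hoxb3 (1.80) the Hox genes. These sums move with the mix of cell types: head and pharyngeal mesenchyme-like cells numbered 0 and 1105 in controls and 634 and 1583 in RA-exposed libraries at E8.75 and E9.25, and proepicardium-like cells 0 and 383 against 426 and 1278. Neural ectoderm-like cells numbered 1231 in the E9.25 control and 0 in the RA-exposed library. A count of 0 means that no cluster met the name, not that such cells were absent. Unnamed clusters held 984 cells in the E8.75 control and 1461 in the RA-exposed E9.25 library. Over all cells 10 of 22 lists passed camera and 0 with an estimated correlation, where the lowest adjusted p was 0.422. Without 1 stage pair the test called between 1 and 892 genes over all cells.

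Neural crest-like cells showed the largest Hox values of the classes tested. All 7 Hox genes measured there rose adjusted over the list alone, although none over all genes, with a median of 3.21 (camera adjusted p = 2.5e-11, and adjusted p = 0.398 with an estimated correlation). Hoxb3 (4.55), Hoxb4 (4.30), Hoxa3 (3.22) and Hoxa2 (3.21), which pattern the hindbrain and its crest, led the list. The class held 199, 369 and 207 control and 235, 173 and 872 RA-exposed cells in stage order. Neural ectoderm-like cells numbered 1231 in the E9.25 control, while no cluster of the RA-exposed E9.25 library met that name. A difference in which cells were named neural crest was not separated from a change within them. Of 15 retinoic acid response genes there, 7 rose adjusted over the list alone and none over all genes, with a median of 1.12 (camera adjusted p = 5.3e-09, and adjusted p = 0.446 with an estimated correlation), among them Hoxb1 (2.79), Meis1 (2.46), Tshz1 (2.43) and Crabp1 (2.29). In pharyngeal and foregut endoderm-like cells the 11 Hox genes had a median of 1.38, 7 rising adjusted over the list alone (camera adjusted p = 2.4e-08, and adjusted p = 0.75 with an estimated correlation). The retinoic acid response list there had a median of 0.55 with 6 up and 1 down adjusted over the list alone. Its median was 0.19 in endothelium, 0.84 in hepatic and yolk sac endoderm, 0.06 in paraxial mesoderm and 0.14 in surface ectoderm, where camera did not pass.

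Few single genes passed in these classes. AC160336.1 fell in endothelium-like (-6.33), neural crest-like (-6.33), paraxial mesoderm-like (-6.01), pharyngeal endoderm-like (-6.18) and surface ectoderm-like cells (-6.92). Usp50 fell in endothelium (-3.02), paraxial mesoderm (-3.09), pharyngeal endoderm (-3.14) and surface ectoderm (-3.18), and H2-T23, a class Ib histocompatibility gene, in endothelium (-4.23) and surface ectoderm (-3.76). Ttr, the transthyretin of yolk sac and liver, fell in neural crest (-3.59), and its source there was not tested. Hepatic and yolk sac endoderm-like cells numbered 1458, 402 and 124 in controls and 144, 175 and 267 in RA-exposed libraries, in stage order. Without the E8.25 pair 0 of the 2 genes named in neural crest kept their call. The edgeR quasi-likelihood test called 12 genes in endothelium, 2 each in neural crest, paraxial mesoderm and pharyngeal endoderm and 4 in surface ectoderm. In hepatic and yolk sac endoderm-like cells it called 0 of 11646, with 732 at an unadjusted p under 0.05, and with DESeq2 size factors it called 0 with 742. Without 1 stage pair the counts ranged from 66 to 285 in endothelium, 0 to 724 in hepatic endoderm, 0 to 56 in neural crest, 1 to 193 in paraxial mesoderm, 3 to 304 in pharyngeal endoderm and 11 to 119 in surface ectoderm.

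The reporter was read in controls, whose counts include EGFP, to see which classes hold Foxa2-lineage cells. With each cell thinned to 5000 UMIs, 90.6%, 91.4% and 93.1% of pharyngeal and foregut endoderm-like cells had an EGFP UMI, from the earliest stage to the latest. Of cardiomyocyte-like cells 24.4% (19.9 to 29.2), 19.7% (17.2 to 22.4) and 15% (13.6 to 16.4) did. Erythroid-like cells, taken as background, stood at 9.38%, 5.00% and 4.56%, and neural crest-like cells at 5.03%, 2.87% and 5.21%. Median depths were 25131, 44315.5 and 21654 UMIs in cardiomyocyte-like and 38605, 53464 and 23482 UMIs in erythroid-like cells. Thinning left out 7, 45 and 47 cardiomyocyte-like and 3, 1 and 1 erythroid-like cells. Without thinning the cardiomyocyte shares were 36.8%, 36.9% and 25.4%, and the erythroid shares 30.3%, 20.8% and 14.8%.

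Within the cardiomyocyte-like cells of the E9.25 control, ventricular-like sub-clusters held more EGFP-positive cells than the others. Of ventricular-like cells 29.3% (25.7 to 33.0) had an EGFP UMI, against 10.2% (7.54 to 13.4) of outflow tract-like and 7.57% (5.61 to 9.94) of atrial and venous pole-like cells. At E8.75 the atrial and venous pole-like share of 5.41% (3.19 to 8.53) was at the erythroid background. At E8.25 the ventricular-like and outflow tract-like shares were 23.2% (15.1 to 32.9) and 15.3% (7.88 to 25.7), whose intervals overlap. Foxa2 itself was detected in 0.573%, 0.106% and 0.517% of thinned control cardiomyocyte-like cells, against 0.721%, 0% and 0.967% of erythroid-like cells, where 0 of 100 cells allows a share of up to 3.00%.

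**Figure D4:**
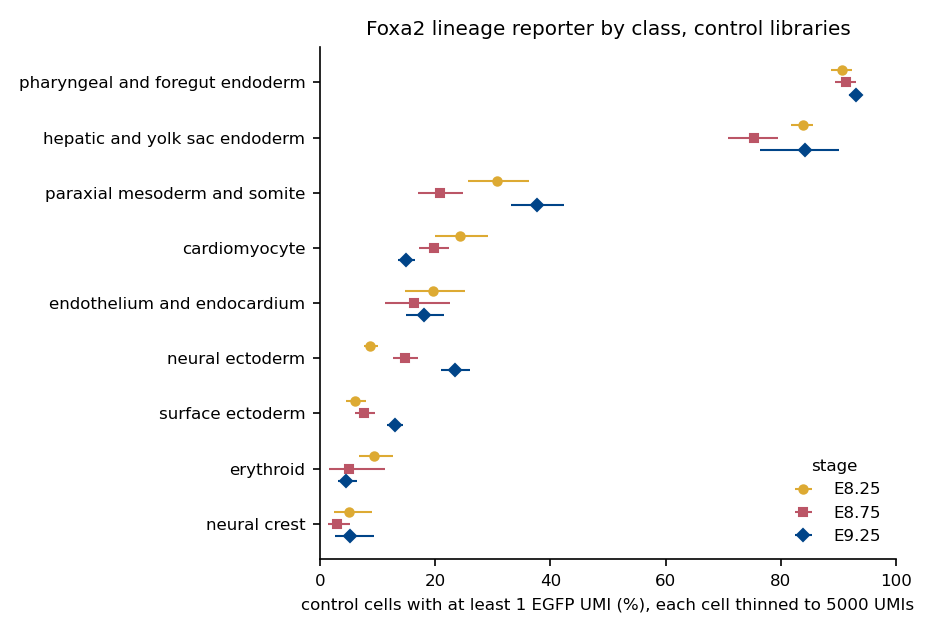
Percent of control cells with at least 1 EGFP UMI after thinning to 5000 UMIs, by class and stage, 1 library per stage. Error bars are exact 95% binomial intervals for counting error. Pharyngeal endoderm-like cells lie between 90.6% and 93.1%, cardiomyocyte-like cells between 15% and 24.4% and erythroid-like cells, the background, between 4.56% and 9.38%.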

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

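The tests chosen only after the result was seen were the comparison of lowered genes between cardiomyocytes and the other classes, the counts over other splits of the libraries and the fit to cells typed as male, whose number of called genes was known before its fold changes were compared. The removal of the length trend was chosen once the trend had been seen, and the search for near-identical genes once the lowered genes had been. Intervals on ratios of fold changes in this section are 95% intervals from 2000 resamples of the genes. They cover the spread among genes, which are not independent, and not the spread between libraries.

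Several values went one way in cardiomyocyte-like cells at some stages and the other way at others, with 1 library per group, and none of these differences was tested. The log2 ratio of the cardiomyocyte-like share, RA-exposed over control, was 1.36 at E8.25, -0.43 at E8.75 and -0.65 at E9.25. The median log2 ratio of sarcomere genes was 0.31, -0.39 and -0.35. That of S phase genes was 0.31, -0.50 and 0.27. That of dissociation and heat stress genes was 0.86, -0.57 and 0.80. That of haemoglobin genes was -2.86, 1.13 and -1.89.

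Over the stages together, long transcripts sat higher in the RA-exposed libraries. Across genes, which are not independent replicates, Spearman's rho of fold change with transcript length was 0.473 in cardiomyocyte-like cells. It was between 0.264 and 0.425 in the 6 other classes. Within E8.75 alone rho was 0.260 in cardiomyocyte-like cells and ranged from 0.061 (pharyngeal endoderm) to 0.285 (hepatic endoderm) in the others. It was 0.077 in neural crest and 0.063 in surface ectoderm, where the longest transcripts sat no higher than the shortest. Between control libraries of 1 software version (E9.25 over E8.25) rho ran from -0.060 in cardiomyocyte-like cells to 0.218 in hepatic endoderm. Because each software version holds 1 treatment, batch and treatment cannot be told apart. The trend alone is argued against as the cause for the retinoic acid response and Hox lists, whose medians kept 0.926 (0.671 to 1.49) and 1.14 (1.01 to 1.21) of their size with it removed, at camera adjusted p = 1.7e-05 and 1.9e-05 with the preset correlation. Before that removal both had an adjusted p = 0.375 with an estimated correlation. For extracellular matrix and oxidative phosphorylation genes, which kept 0.519 (0.152 to 0.730) and 0.644 (0.183 to 0.713), the spread of members keeps the question open, since a response to retinoic acid and a difference between batches may both contribute.

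Genes lowered in RA-exposed cardiomyocyte-like cells were lowered in other classes too, apart from Gal, which was not tested elsewhere. Of the 20 such genes 7 share most of their 3' windows with another gene, against a median of 0 and a 95th percentile of 2 in random sets matched on expression, and 0 of 10000 sets held as many. A change in cardiomyocytes alone is argued against by the other classes, whose fold was 0.898 (0.815 to 1.04) of that in cardiomyocyte-like cells, as a median over 19 genes. A difference in how reads shared by near-identical genes were counted is thus a candidate explanation for Usp50, Gstp1, Hist1h2ae, Eno1, Eno1b, Hmga1 and 1 gene outside the naming rule. Other genes, such as Ccdc85b and AC160336.1, were lower in all 6 other classes. For them a change by retinoic acid in all tissues and a batch difference stay open. For AC160336.1 so does a difference in how its locus was annotated for counting, which was not tested. Mhrt and Carmn were tested in only 2 other classes and Lgals2 in 3, where they were lower, and Gal in 0. For these genes a change mainly in cardiomyocytes stays open too. Apoa1 and Apob are yolk sac and liver transcripts, and RNA or cells from that source were not separated here.

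The pools differed in sex, as Xist and Y-linked genes show. If that caused the calls, fold changes would shrink in cells of 1 sex, but in cells typed as male the fold of the 44 called genes outside the sex-linked list that were also measured there was 0.990 (0.973 to 1.02) of that in all cells, as a median, and 44 kept their sign. Single genes ranged from 0.379 to 1.19 of their fold. Sex makeup is thus argued against as the cause of these calls as a set, whereas Xist follows it by construction. The biological explanation left by the design, retinoic acid, was not separated from batch.

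With 10 splits of the 6 libraries, a share under 0.05 cannot be reached. The real split called 47 genes in cardiomyocyte-like cells against at most 0 in the others, 1 over all cells against 0, 12 in endothelium against 1 and 4 in surface ectoderm against 0, so that in each of these 1 split gave as many. In neural crest and in paraxial mesoderm the real split called 2 genes against up to 151 and 265, and in pharyngeal endoderm 2 against up to 26, with 3 splits giving as many in each. In hepatic and yolk sac endoderm it called 0 against up to 4302, and all 10 splits gave as many. These high counts came only from splits unbalanced over the stages, and among the 4 balanced ones, the real one included, the highest other count was 0 in these 4 classes. With stage as block, an unbalanced split varies only within 1 stage, where it sets the control against the RA-exposed library. These high counts thus reflect how the pair of libraries of 1 stage differs, without replicates, and no conclusion is drawn from them.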

How the results depend on the processing

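Alternatives chosen only after the data were seen were male cells, sex-linked genes left out, the length trend removed, joint clustering, low-UMI clusters left out, second closest clusters added and sub-clusters led by outside markers left out. The cause was not tested for any value below. No paired analysis was possible because every group has 1 library, with replicate number 1, other than by stage, which pairs the libraries as the block of the RA comparison.

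In cardiomyocyte-like cells the RA comparison called 47 genes. DESeq2 size factors gave 92, the DESeq2 Wald test 903, no filter 1439, doublets kept 7 (1 up, 6 down), looser cell filters 17, stricter ones 16, Leiden resolution 2 132, markers left out of clustering 25 and no block 3 (0 up, 3 down). Leaving out a stage pair gave 151 to 1043. Joint clustering gave 625, low-UMI clusters left out 125, second closest clusters added 263 and the length trend removed 28. Thinning gave 42, male cells 41, outside sub-clusters left out 42 and sex-linked genes left out 63. Of the named genes, 6 were still called with doublets kept, 10 with looser and 9 with stricter cell filters, 3 without block and 12 with the length trend removed. Over all cells the Wald test gave 1664, no filter 23, leaving out a stage pair 1 to 892 and no block 0, against 1. The stage comparison gave 2141 without filter, 3217 without the E8.75 pair, 863 with doublets kept and 773 in male cells. Leaving out a stage pair gave 66 to 285 in endothelium, 0 to 724 in hepatic endoderm, 0 to 56 in neural crest, 1 to 193 in paraxial mesoderm, 3 to 304 in pharyngeal endoderm and 11 to 119 in surface ectoderm.

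The log2 ratio of the cardiomyocyte-like share at E8.25 was 1.16 with looser and 0.64 with stricter cell filters, 1.85 with markers left out of clustering, 6.37 with joint clustering (9 control cells), 0.88 with low-UMI clusters left out, 1.85 with second closest clusters added and 1.12 with outside sub-clusters left out. At E8.75 it was -0.11 with looser filters, -0.13 with low-UMI clusters left out, 0.17 with second closest clusters added, which turns its sign, and -0.20 with outside sub-clusters left out. At E9.25 it was -0.53 with looser filters and -0.76 with low-UMI clusters left out. Sarcomere genes at E8.25 turned to -0.16 with second closest clusters added. In male cells Eif2s3y turned to 0.10 and Kdm5d to 0.36. With an estimated correlation 0 lists passed in each comparison, against 11, 10 and 10. Without thinning, EGFP was found in 36.8%, 36.9% and 25.4% of control cardiomyocyte-like cells.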

Other observations

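The split of cardiomyocyte-like cells by EGFP was chosen after the reporter shares were seen, and it was not tested. In control cardiomyocyte-like cells those with an EGFP UMI numbered 131, 365 and 650, and those without 225, 623 and 1911, in stage order. Ventricular genes were higher in cells with EGFP at the later stages: the list's median log2 ratio was 0.04 at E8.25, 0.40 at E8.75 and 0.41 at E9.25, at percentile 79.7 of random lists at first and above all of them at the later stages. Cited1, a transcriptional cofactor of ventricular muscle, had a mean log2 ratio of 0.82 over the stages, Nppa of 0.60, the ventricular repressor Hey2 of 0.45 and Hand1, a factor of the left ventricle, of 0.40. Atrial and sinus venosus genes stood at -0.0031, -0.46 and -0.36. Nr2f1 (-0.69), Vsnl1 (-0.51), Stard10 (-0.46) and Nr2f2 (-0.44) had the largest mean differences of that list among members with at least 10 CPM, and Nr2f1 and Nr2f2 are nuclear receptors of atrial identity. S phase genes stood at -0.04, 0.11 and 0.15, above all random lists at the later stages and with 20 of 20 higher at E9.25, and genes of G2 and mitosis at 0.22, -0.04 and 0.10. Sarcomere genes stood at -0.11 at E8.25 and -0.08 at E9.25, and BMP genes at -0.27 at E8.75 and -0.22 at E9.25. Retinoic acid response genes stood at -0.31 at E8.75 and second heart field genes at -0.22 at E9.25. Each of these values lay below all random lists. At E8.25 BMP, retinoic acid response and second heart field genes stood at 0.0034, 0.0077 and 0.11 (percentiles 48.0, 46.6 and 95.2). At E8.75 sarcomere genes stood at -0.03 (3.69) and second heart field genes at -0.12 (0.24). At E9.25 retinoic acid response genes stood at -0.08 (4.32). Most genes of the ventricular and of the atrial and sinus venosus list also named the chamber sub-clusters. These list values are thus not independent of the EGFP shares of those sub-clusters. Cells with an EGFP UMI were read without thinning, so that deeper cells enter that side more often. At E9.25 the median depth was 27296.5 UMIs in ventricular-like, 20142 in atrial and venous pole-like and 18365 in outflow tract-like cells. At E8.25 it was 23479 in ventricular-like and 24579 in outflow tract-like cells. Erythroid-like cells, as background, had an EGFP UMI in 30.3%, 20.8% and 14.8% without thinning, against 36.8%, 36.9% and 25.4% of cardiomyocyte-like cells. Much of the side with EGFP can thus be background, and depth and cell cycle were not separated from lineage here.

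Outside the heart, 88.5% (80.7 to 93.9) of notochord-like cells of the E8.25 control had an EGFP UMI after thinning, and Foxa2 itself was found in 40.4% of them. Hepatic and yolk sac endoderm-like cells stood at 83.8%, 75.4% and 84.2%, endothelium-like cells at 19.6%, 16.4% and 18.1% and paraxial mesoderm-like cells at 30.8%, 20.8% and 37.7% in stage order. The reporter allele mTmG loses tdTomato where Cre acted: tdTomato was found in 0.192%, 0% and 0.36% of pharyngeal endoderm-like cells and in 2.58%, 6.47% and 2.67% of cardiomyocyte-like cells. Erythroid-like cells, the background for EGFP, had tdTomato in 1.20%, 3.00% and 0.691%. They are no background for tdTomato, which is kept where Cre did not act. Detection was low in all of these classes, so the shares do not measure how many cells Cre left unchanged.

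Sarcomere genes in classes outside the heart muscle were lower in RA-exposed than in control libraries in neural crest (median -0.82), paraxial mesoderm (-0.76), endothelium (-0.59), surface ectoderm (-0.49) and pharyngeal endoderm (-0.35), and higher in hepatic and yolk sac endoderm (0.30). Whether this RNA is free RNA, comes from undetected doublets or is the cells' own was not tested.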
